A study of Danio rerio
Oryzias latipes and Oryzias latipes and Danio rerio with 7 samples.

How the data were processed

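RNA was measured in 7 libraries of whole embryos: 2 of medaka (Cab), 2 of zebrafish (AB) and 3 of chimeras made by transplanting zebrafish blastomeres into medaka blastulae of matching age. RNA was taken with Trizol and selected for poly(A) with a NEBNext module before sequencing. The deposited FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments of the library on that genome) were made by the authors with HISAT2 and Cufflinks 2.2.1. Each library has a table of FPKM with confidence limits for 32264 zebrafish gene IDs (danRer10) and another for 20459 medaka gene IDs, so 14 tables were used. The HISAT2 version and the medaka genome build are not given in the sources used here. All zebrafish IDs and 14683 medaka IDs carry a symbol, and 26433 zebrafish IDs were found in the table of gene names. Positions are those of the files with the start counted from 1. IDs at several loci, 119 in zebrafish and 2 in medaka, had their values summed.

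Fragments behind each value were worked out as the square of 2 times FPKM over the distance from FPKM to its upper confidence limit. This holds where the limits follow counting error. For genes with several isoforms the limits are wider, so the number is then too low. Totals per library are given at the start of the results. A gene was taken as under the floor when it neither held 3 fragments per chimera on average nor would have held them at its control level. Such floors cover counting error only.

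FPKM were rescaled by the median ratio between libraries and taken as log2(FPKM + 1). Tested genes had a mean FPKM of at least 1 in either group and under 1 in the other species' libraries on the same genome, which removed 738 zebrafish and 923 medaka genes for cross-mapping. A further 54 and 4 genes were left out because Cufflinks gave no valid status. limma 3.58.1 (R 4.3.3; linear fit, empirical Bayes with trend and robust options) tested chimeras against zebrafish embryos on the zebrafish genome, chimeras against medaka embryos on the medaka genome, the interaction of both over genes with the same symbol, and zebrafish against medaka embryos. P-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. The other species' libraries served only for the filter. With 2 against 3 libraries the smallest two-sided exact permutation p is 0.1. Tables were read and figures drawn with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

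Gene lists, the rule for named genes, the tests and most alternatives were chosen before the data were examined. The 29 lists hold 660 entries for 653 genes, 7 of them in more than 1 list, and 652 entries were matched in zebrafish and 446 in medaka by symbol without regard to case. Matching by alias was made stricter after results had been seen: an alias that is another gene's own symbol no longer counts, which removed wrongly matched genes. A symbol held by several gene records counts once per record. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Germ cell genes had too few tested members in either genome, and retinal differentiation genes too few in the host.

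Named genes have a symbol, an adjusted p under 0.05, a mean FPKM of at least 10 in the higher group and groups that do not overlap. The 10 with the largest increase and the 10 with the largest decrease were taken per main comparison, and 5 in each direction for the other comparisons. In addition, up to 4 members with the smallest p were taken per called list, and every tested member of the eye field list, of which 1 gene is not reported here by itself, although the tests of its list include it. Any other named gene was chosen after its value was seen. Gene families by symbol stem, with at least 8 members, were looked at after the data were seen.

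The share of donor fragments is the zebrafish-genome fragments of a chimera, less the cross-mapping rate of the medaka libraries (0.475% and 0.424%), over the fragments of both genomes. Non-negative least squares fitted the zebrafish-genome profile of each chimera, and the zebrafish coefficient is given as a percentage of the sum of both coefficients. Alternatives covered the pseudocount (0.1 and 5), expression and cross-mapping filters, scaling, each library left out, all 3 groups in a fit, the library as a block, and the list test. Added after the data were seen were voom weights on the implied fragments, libraries thinned to a common depth, a set without small noncoding RNA genes, other cross-mapping rates, and a set over the floor.

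The tests were tried on simulated data with 200 changed genes at a dispersion of 0.02. In the donor comparison 80% of genes raised 4-fold were called, 29.2% of those lowered 4-fold and 6% of those raised 2-fold. Of the calls, 96 were false (61.1%), 95 of them on genes under the floor. Over the floor 1 call was false (1.82%). In the host 94% of genes raised 2-fold and 90% of those lowered 2-fold were called, with 31 false calls (14.0%). False calls were 10.6% of calls for the difference between donor and host and 8% for the species. Because of this, no fold is given for donor genes at or near 0 in the chimeras, and the medians of called lists with genes at 0 are also given at the floor.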

Results

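The series compares 3 kinds of whole embryo by RNA sequencing. They are medaka embryos of the Cab strain (n = 2 libraries), zebrafish embryos of the AB strain (n = 2) and chimeras called zebraka (n = 3), which are medaka blastulae that received zebrafish blastomeres of matching age. All were raised at 28 °C, the zebrafish in E3 medium and the others in ERM, a medaka rearing medium. The stage is given only as embryo. Each of the 7 libraries comes as a gene table against the zebrafish genome and another against the medaka genome, so the chimeras' donor and host transcripts can be read apart. Nothing in the labels says that the libraries of a group came from separate clutches or pools. The p-values therefore measure only the spread between these samples, which may be technical.

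Fragment numbers below are those implied by the deposited confidence limits. On the zebrafish genome the zebrafish libraries held 21866700 and 28574200 fragments, the chimeras 941708, 764000 and 847288, and the medaka libraries 102064 and 77794. On the medaka genome the medaka libraries held 21491600 and 18330400, the chimeras 30984000, 27167700 and 27824200, and the zebrafish libraries 63818 and 81765. Over zebrafish genes with almost no cross-mapped medaka signal, the medaka libraries held 31.9 and 121 fragments, and the chimeras 633287, 505252 and 561703. These genes were chosen for a low signal in the medaka libraries, so the difference is described and not tested. After the cross-mapping of the medaka libraries was taken off, zebrafish transcripts made up 2.45% ± 0.127 of chimera fragments (SD, n = 3), with a range of 2.31% to 2.53%. The SD leaves out any bias between the genomes. In the chimeras 28.9% to 29.7% of low implied fragment numbers were whole on the zebrafish genome, against 58.9% to 59.2% on the medaka genome. The undercount for genes with several isoforms may therefore differ between them. The chimeras' zebrafish-genome profile was also written as a weighted sum of the zebrafish and the cross-mapped medaka profile. The zebrafish coefficient was 86.7% ± 1.86 of the sum of both coefficients (SD, n = 3). It was 68.5% with abundant genes weighted down and 73.3% without the 100 most abundant genes. This is not a share of FPKM, because the cross-mapped profile sums to more FPKM than the zebrafish profile. Per unit of FPKM the zebrafish libraries were 43.1-fold deeper than the chimeras, so weakly expressed donor genes were measured far less precisely than host genes.

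The first comparison asks which zebrafish genes the transplanted cells expressed in a medaka embryo, against whole zebrafish embryos. Rearing medium, ERM for the chimeras and E3 for the zebrafish embryos, differs together with transplantation here. The donor transcripts were rich in retinal genes and poor in those of most other tissues, although no list was called with an estimated correlation between genes (lowest adjusted p = 0.055). Of the 10 named genes with the largest increase, otx5 and crx, homeobox genes of photoreceptors and their precursors, went from 1.60 ± 0.273 to 57.0 ± 5.91 FPKM and from 1.49 ± 0.214 to 44.6 ± 5.55 FPKM. These are rescaled means ± SD, with n = 2 zebrafish libraries and n = 3 chimeras here and for all donor values that follow. They were 35.6-fold and 30.1-fold higher. pde6g, a subunit of the phototransduction phosphodiesterase, rose 26.1-fold to 95.7 ± 8.69 FPKM. rorb, a nuclear receptor of the retina, rose 18.3-fold, prdm1b 29.7-fold and foxg1b, a forebrain regulator, 17.8-fold. The uncharacterised gene si:dkey-238o13.4, at 14703277 to 14709424 on chromosome 18 (danRer10), had the largest difference on the log2(FPKM + 1) scale, from 6.1 ± 1.59 to 250.2 ± 10.3 FPKM (41.0-fold; 5.16, SE 0.16; adjusted p = 7.1e-05). The other 3 were si:dkey-21o19.2 at 44.1-fold, ndrg1b at 64.2-fold and sept4a at 26.9-fold. prdm1b, pde6g and crx each share their symbol with another gene record, so their values could be split between records.

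The 10 named genes with the largest decrease belonged to yolk, skin, muscle and blood. apoa2, a yolk lipoprotein gene, stood at 3220 ± 163 FPKM in zebrafish embryos and was listed at 0 in all 3 chimeras, although 319 fragments would have been present at the zebrafish level. afp4 (1988 ± 55.1 FPKM), the epidermal calcium-binding genes icn (1905 ± 259) and icn2 (1088 ± 159), the fast muscle genes tnni2a.4 (1626 ± 556) and mylpfb (1429 ± 418), the embryonic globin hbbe3 (1432 ± 114) and the lipid carrier fabp1b.1 (1106 ± 64.3) were also listed at 0 in each chimera, as was the other gene record named afp4 (563 ± 29.8). apoc1 went from 1836 ± 146 to 0.311 ± 0.538 FPKM and tnnt3a from 895 ± 247 to 0.200 ± 0.346 FPKM, both on under 1 fragment over the 3 chimeras. No fold is given for genes at or near 0. None of 73 ribosomal protein genes was listed at 0 in any chimera, and the lowest stood at 84.8, 106 and 80.4 FPKM. These genes are abundant and were not filtered for cross-mapped medaka reads. Of the 19 rpl and 16 rps genes tested after that filter, 0 were at 0 in all chimeras. The check does not cover weakly expressed genes.

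Over 16556 tested zebrafish genes, 1744 rose and 5378 fell in the donor cells by limma's moderated test with Benjamini-Hochberg adjustment. Of these, 540 rose and 4412 fell by at least 2-fold on the log2(FPKM + 1) scale. The median over all tested genes was -0.23, and 1907 of the fallen genes were listed at 0 in all 3 chimeras. The groups did not overlap for 65.6% of genes, against 20% by chance if the libraries could be exchanged. They cannot be here, because at the lower depth of the chimeras an unchanged weak gene can be at 0 in each. The balance of directions rests on the scaling. Quantile normalization moved the median of all genes to 0.30, and voom weights on the implied fragments, added after the data were seen, to -0.51. The former gave 5387 higher and 3307 lower genes, so 62.0% of called genes were higher in place of 24.5%. Without zebrafish replicate 1 the counts were 628 higher and 3339 lower, and without zebrafish replicate 2 they were 758 and 3331. Without an expression filter 9450 genes were lower, and at a minimum mean FPKM of 5 there were 3083. Testing only genes that held, or should hold, at least 3 fragments per chimera on average gave 1805 higher and 4818 lower of 14485. That choice was added after the test was tried on simulated data.

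Among the lists of marker genes fixed in advance, the eye field and retinal progenitor list had the highest median. Of its 23 tested members 20 rose and 2 fell, with a median of 1.89 on the log2 scale (21 risen and 2.32 under quantile normalization). pax6a, a master regulator of eye formation, rose 7.44-fold from 39.0 ± 1.28 to 290 ± 18.6 FPKM. atoh7, needed for retinal ganglion cells, rose 15.2-fold to 169 ± 6.17 FPKM, and vsx1, a bipolar cell gene, rose 12.9-fold to 89.2 ± 8.19 FPKM. six7, a regulator of green cones, rose 63.9-fold to 14.8 ± 0.839 FPKM. Among other members the log2 changes were 2.83 for hmx1, 2.58 for six6b, 2.48 for pax6b, 2.30 for tbx2b, 2.05 for hmx4, 2.04 for rx1, 1.89 for vax2, 1.85 for rx2, 1.84 for six3b, 1.70 for ccnd1, 1.66 for aldh1a3, 1.55 for mab21l1, 1.26 for lhx2b, 0.98 for six6a and 0.59 for vax1. mab21l2 at -1.04 and foxd1 at -1.05 fell, and rx3, an early eye field gene, stood at 0.31 with an adjusted p of 0.48 (1.14 and 0.034 under quantile normalization). Again 20 rose and 2 fell when adjusted over the list alone. camera, a test of a list against all other genes, gave adjusted p = 5.4e-13 with a preset correlation between genes, and adjusted p = 0.083 with an estimated correlation. The calls of mab21l2, foxd1 and vax2 were lost without either zebrafish library (adjusted p = 0.13, 0.14 and 0.12 without replicate 1, and 0.076, 0.097 and 0.082 without replicate 2). That of lhx2b was lost without replicate 1 (adjusted p = 0.059), and those of six6a and rx2 without replicate 2 (adjusted p = 0.054 and 0.051). At matched depth vax1 and six6a lost theirs (adjusted p = 0.11 and 0.18).

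The list of retinal neuron and photoreceptor differentiation followed, with 10 of 13 members risen, none fallen and a median of 1.54 (12 and 1.96 under quantile normalization). Besides otx5 and crx, nr2e3, a nuclear receptor of rods, rose 31.8-fold from 0.868 ± 0.225 to 27.6 ± 3.77 FPKM, and neurod4 rose 3.74-fold from 66.0 ± 9.01 to 247 ± 8.58 FPKM. The count was again 10 when adjusted over the list alone, and camera gave adjusted p = 1.0e-07, and adjusted p = 0.088 with an estimated correlation. The retinal pigment epithelium and melanin list went the other way, with 10 of 12 members fallen, none risen and a median of -1.36 (6 and -0.82 under quantile normalization). It pools genes of the pigment epithelium and of melanin, against whole embryos, so a lack of pigment epithelium cannot be read from it. The pigment enzyme tyrp1b fell 6.82-fold from 42.6 ± 8.82 to 6.24 ± 0.507 FPKM, and dct fell 2.94-fold from 32.3 ± 2.87 to 11 ± 1.59 FPKM. tyrp1a fell 4.79-fold, and mitfa, the regulator of melanocytes, went from 5.65 ± 0.140 to 0.860 ± 0.476 FPKM on 1.39 fragments, calls that were lost without zebrafish replicate 1 (adjusted p = 0.091 and 0.074) or replicate 2 (0.058 and 0.066). Likewise 10 fell when adjusted over the list alone, and camera gave adjusted p = 0.024, and adjusted p = 0.15 with an estimated correlation. That call was lost without zebrafish replicate 1 (adjusted p = 0.20), without replicate 2 (adjusted p = 0.15) and without an expression filter (adjusted p = 0.063).

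**Figure D1:**
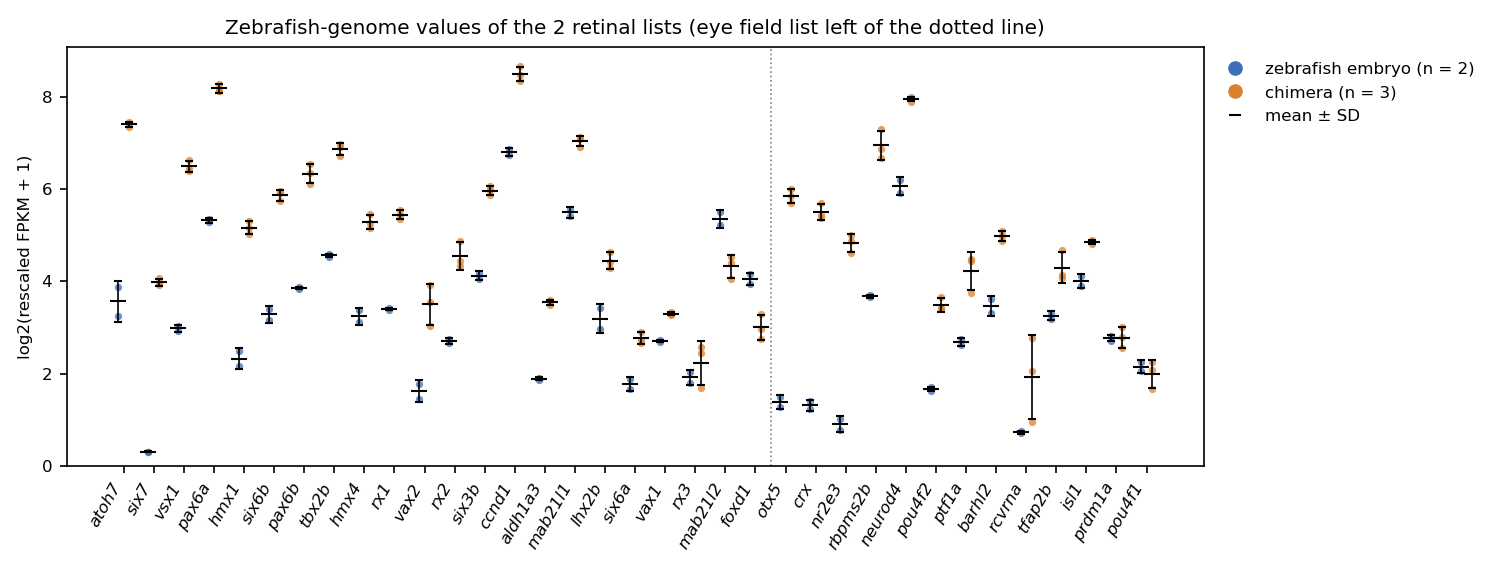
Each point is 1 library's zebrafish-genome value, as log2(rescaled FPKM + 1), for tested members of the eye field list (left of the dotted line) and the retinal differentiation list (right), in zebrafish embryos (n = 2) and chimeras (n = 3). Bars are means ± SD. The widest gaps include that of otx5, which rose 35.6-fold.

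Lens genes fell in the donor cells, with 12 of 13 members lower and a median of -4.89, or -3.12 with the 7 genes at 0 set to the level of 3 fragments per chimera (10 and -4.34 under quantile normalization). The crystallins cryba1b (218 ± 68.4 FPKM) and cryba2a (136 ± 33.7), the lens membrane gene lim2.1 (48.0 ± 7.07) and the lens channel mipa (35.8 ± 4.59) were listed at 0 in all 3 chimeras. prox1a, which acts in the retina as well as the lens and was named after its value was seen, rose 3.27-fold. camera gave adjusted p = 3.1e-04, and adjusted p = 0.23 with an estimated correlation, and 1 rose and 12 fell when adjusted over the list alone.

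Donor brain genes were tested as 2 lists, which were not tested against each other. In the forebrain list 6 of 23 members rose and 7 fell, with a median of -0.27 that became 0.11 under quantile normalization and a mean of -0.12. camera pointed upward without a call (adjusted p = 0.19; 0.53 with an estimated correlation), and 9 rose and 9 fell when adjusted over the list alone. Chosen after their values were seen, otx2, a gene of the anterior brain and eye, stood at 142 ± 7.39 FPKM against 21.0 ± 1.5, and nkx2.1, a gene of the ventral forebrain, was listed at 0 in every chimera against 6.03 ± 0.259. In the midbrain and hindbrain list 15 of 24 members fell and 1 rose, with a median of -1.46, or -1.26 with 3 genes at their floor. Under quantile normalization 12 fell, 5 rose and the median was -0.79. The hindbrain genes hoxb3a (40.7 ± 2.43 FPKM), hoxb1b (16.0 ± 1.23) and hoxb1a (3.29 ± 0.0643) were listed at 0 in all chimeras, and hoxa3a went from 57.6 ± 2.62 to 0.188 ± 0.164 FPKM on under 1 fragment. The riser was fgf8a, a signal of the midbrain-hindbrain boundary and of the early retina, named after its value was seen (1.36). The counts were 1 and 15 again when adjusted over the list alone. camera gave adjusted p = 0.0039, and adjusted p = 0.096 with an estimated correlation, and without zebrafish replicate 2 the adjusted p was 0.056. Each of the 33 posterior hox genes tested fell, and 31 were listed at 0 in all chimeras, of which 29 would have been over the floor at the zebrafish level. hoxc3a stood at 42.6 ± 2.16 FPKM in the embryos, hoxb9a at 22.1 ± 3.02, hoxb8a at 21.9 ± 2.55 and hoxd3a at 19.5 ± 0.938. Despite the list's name, hoxc3a and hoxd3a are group 3 hox genes, as are hoxb3a and hoxa3a of the hindbrain list. The hox median was -3.43, or -1.84 at the floor, with adjusted p = 1.6e-13 and adjusted p = 0.27 with an estimated correlation, and all 33 fell when adjusted over the list alone. Under quantile normalization 31 hox genes fell and the median was -2.75.

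Cell cycle and DNA replication genes rose together, 32 of 36 with none fallen and a median of 0.88 (34 and 1.01 under quantile normalization). rrm1, a subunit of the enzyme that makes deoxyribonucleotides, rose 2.51-fold from 134 ± 1.07 to 336 ± 9.05 FPKM. The 2 gene records named rrm2, the enzyme's other subunit, rose 2.54-fold and 2.30-fold, and mki67, a proliferation marker, rose 2.30-fold from 83.0 ± 7.15 to 191 ± 5.12 FPKM. When adjusted over the list alone, 34 rose. camera gave adjusted p = 6.4e-16, and adjusted p = 0.055 with an estimated correlation. Neural progenitor and neuron genes split, with 7 of 27 risen and 5 fallen around a median of 0.11. insm1a, a regulator of newly forming neurons, rose 5.35-fold to 305 ± 21.6 FPKM, neurod1 4.66-fold, the Notch ligand dlc 4.16-fold and olig2 2.59-fold. The counts stayed at 7 and 5 when adjusted over the list alone. camera gave adjusted p = 0.030 (upward), and adjusted p = 0.27 with an estimated correlation. This call was lost under quantile normalization (adjusted p = 0.57), at matched depth (adjusted p = 0.056), at a minimum mean FPKM of 5 (adjusted p = 0.12), with only genes at 0 in the medaka libraries (adjusted p = 0.065), without medaka replicate 1 (adjusted p = 0.067) and without chimera replicate 1 (adjusted p = 0.052). Without zebrafish replicate 2 the median was -0.02.

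Muscle, notochord, heart and blood genes were low or unseen in the donor cells. Of 18 somite and skeletal muscle genes 17 fell (median -3.62; -2.81 with 7 genes at their floor), among them the slow myosin smyhc1 (172 ± 16.0 FPKM) and the caveolin cav3 (86.7 ± 15.1), both listed at 0. Of 17 notochord and floor plate genes 16 fell (median -3.42; -2.37 with 6 at the floor). The cartilage and notochord collagen col2a1a fell 118-fold from 292 ± 17.6 to 2.47 ± 0.301 FPKM, and cav1 (44.0 ± 1.25 FPKM) was listed at 0. All 11 heart genes fell (median -3.73; -2.16 with 10 at the floor), including the myosin light chain myl7 (31.2 ± 1.44 FPKM) and the troponin tnnt2a (22.3 ± 1.25). Of 17 erythroid genes 16 fell (median -2.29; -1.77 with 10 at the floor), including the anion exchanger slc4a1a (101 ± 0.630 FPKM) and the heme enzyme alas2 (76.0 ± 0.929), both listed at 0. All 16 myeloid gene records, 5 of them records of mfap4 on chromosome 1, fell (median -1.96; -1.04 with 10 at the floor), including cebpa (8.61 ± 0.00245 FPKM) and mmp13a (4.24 ± 0.355), both listed at 0. At the zebrafish level, 9 of the 10 heart, 9 of the 10 erythroid and 7 of the 10 myeloid records at 0 would have been over the floor, so the others could be at 0 without a change. Adjusted over the list alone, 18 muscle, 17 notochord, 11 heart, 17 erythroid and 16 myeloid records fell. Under quantile normalization 15, 14, 9, 10 and 11 fell in that order, with medians of -2.93, -2.74, -3.10, -1.66 and -0.97. camera gave adjusted p = 3.8e-07, 2.2e-07, 5.8e-06, 1.4e-06 and 1.4e-06 in that order. Each of the 5 had adjusted p = 0.055 with an estimated correlation.

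Genes of the outer and inner epithelia and of the yolk followed the same direction. All 21 epidermis and periderm genes fell (median -5.86; -4.87 with 12 at the floor), with anxa1c (369 ± 21.9 FPKM) and agr1 (171 ± 10.1) listed at 0. All 16 yolk syncytial layer and lipoprotein genes fell (median -7.61; -4.63 with 12 at the floor). Of 10 ionocyte genes 9 fell (median -1.84; -1.30 with 4 at the floor), including foxi3b (6.88 ± 0.119 FPKM), listed at 0. The riser was dlc, a Notch ligand also held by the neuron list (4.16-fold). Of 11 endoderm and gut genes 10 fell (median -2.58; -1.69 with 7 at the floor), including fabp2 (161 ± 1.33 FPKM) and insulin, ins (16.4 ± 0.326), listed at 0. The riser was again prox1a, and 5 of the 7 genes at 0 would have been over the floor at the zebrafish level. Of 17 endothelial genes 13 fell and 2 rose (median -2.39; -1.52 with 6 at the floor). sox7 (5.46 ± 0.445 FPKM) and pecam1 (4.79 ± 0.503) were listed at 0, while sox18 and cldn5b, named after their values were seen, rose by 1.64 and 1.56. Of 29 glycolysis and hypoxia genes 19 fell and none rose (median -1.0). gapdh went from 719.6 ± 168 to 2.15 ± 1.19 FPKM on 2.8 fragments, and tpi1b fell 6.80-fold from 165 ± 27.4 to 24.2 ± 3.09 FPKM. Adjusted over the list alone, 21 epidermal, 16 yolk, 9 ionocyte, 10 endodermal, 13 endothelial and 20 glycolysis genes fell. Under quantile normalization 21, 16, 7, 9, 11 and 16 fell in that order, with medians of -5.34, -7.07, -0.86, -1.74, -1.68 and -0.70, and 1 glycolysis gene rose. camera gave adjusted p = 8.4e-12, 6.3e-10, 0.0075, 4.1e-04, 0.0037 and 8.4e-04 in that order. With an estimated correlation the adjusted p values were 0.055, 0.055, 0.12, 0.083, 0.096 and 0.15. The ionocyte call was lost at a minimum mean FPKM of 5 (adjusted p = 0.21).

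The 9 lists without a call were the forebrain list and 8 others. Of the members tested, 4 of 15 neural crest genes rose and 8 fell (adjusted p = 0.19), 2 of 9 presomitic genes rose and 3 fell (0.49), 1 of 5 hatching gland genes rose and 3 fell (0.16), and 4 of 10 pluripotency and maternal genes fell (0.14). In the p53 list 1 of 17 rose and 6 fell (0.78), in the heat shock list 1 of 24 rose and 10 fell (0.15), in the innate immune list 1 of 10 rose and 6 fell (0.14), and in the retinoic acid list 3 of 14 rose and 8 fell (0.43). Under quantile normalization fewer members fell in most of these lists, among them 2 innate immune genes with 2 risen, and 5 neural crest genes. The retinoic acid risers were cyp26a1 and cyp26c1, which break retinoic acid down, and the receptor rxrgb, with log2 changes of 1.1, 1.27 and 0.74, named after their values were seen. The hatching gland list was called lower without the cross-mapping filter (adjusted p = 0.0090), under quantile normalization (0.049), without medaka replicate 2 (0.0089) and without zebrafish replicate 2 (0.020). So were the heat shock list under quantile normalization (0.027) and the pluripotency list without an expression filter (0.012). In all, 28 donor lists were tested, 4 called higher and 15 lower. None was called with an estimated correlation (lowest adjusted p = 0.055, with 13 under 0.05 before adjustment), and fry, which asks only whether a list moves one way, called 4 higher and 23 lower.

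**Figure D2:**
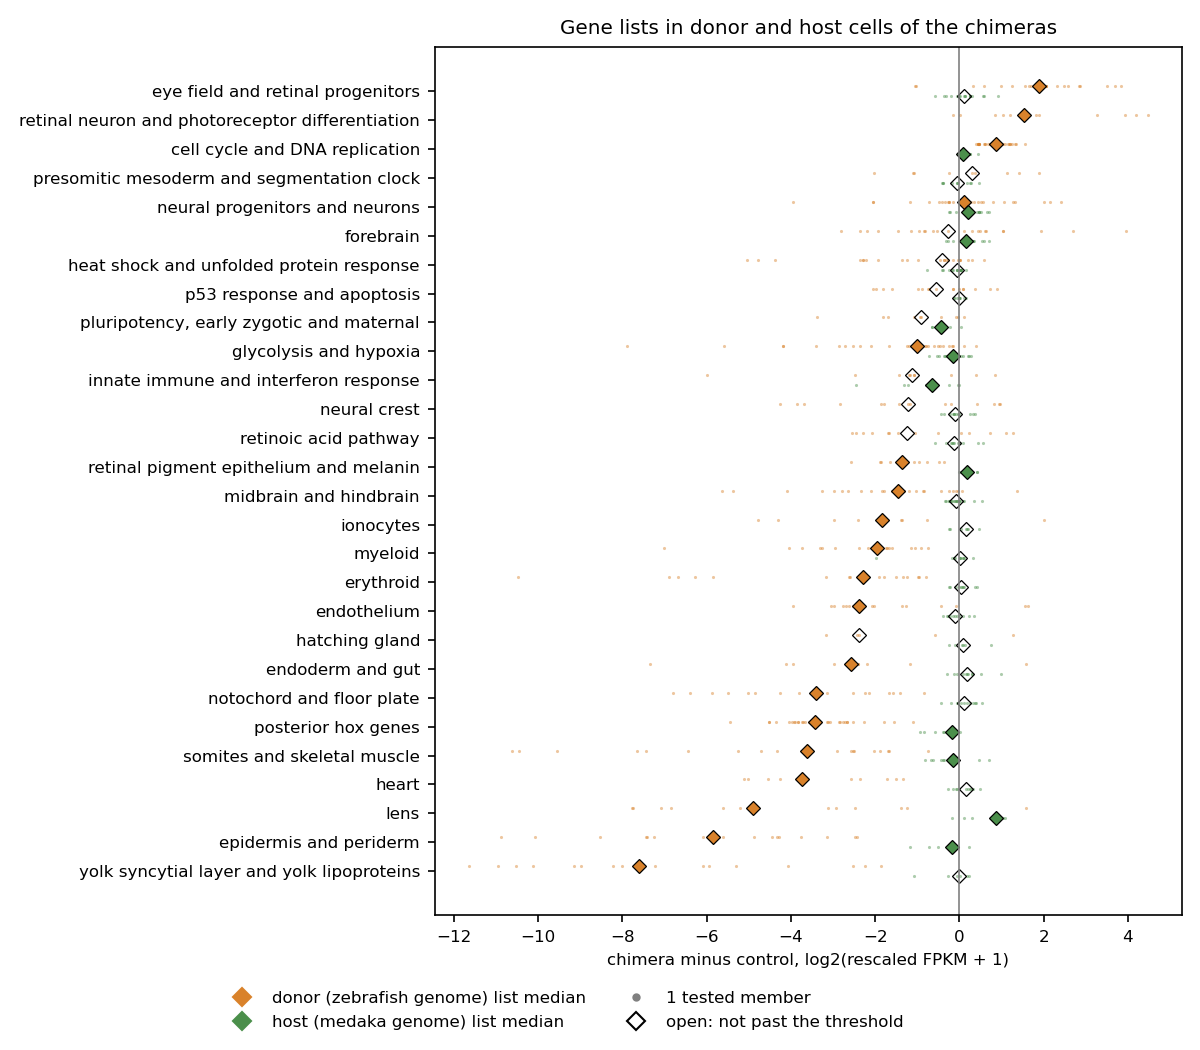
Small points are tested members and diamonds are medians of each gene list, as chimera minus control on the log2(rescaled FPKM + 1) scale, for donor genes (orange, 3 chimeras against 2 zebrafish libraries) and host genes (green, 3 chimeras against 2 medaka libraries). Filled diamonds passed camera at an adjusted p under 0.05. Donor medians run from -7.61 for yolk genes to 1.89 for eye genes, and host medians from -0.66 for innate immune genes to 0.86 for lens genes. With donor genes at 0 set to their floor, the lowest median was that of epidermis genes (-4.87, against -4.63 for yolk genes).

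The second comparison asks how medaka genes differed in embryos that carried zebrafish cells, against medaka embryos. Lens list genes rose and innate immune list genes fell, but neither list was called with an estimated correlation (adjusted p = 0.31 and 0.26). The lens crystallin crygn2 rose 2.05-fold from 47.0 ± 2.94 to 96.5 ± 0.956 FPKM (n = 2 medaka libraries and n = 3 chimeras here and for all host values that follow; 1.02 on the log2 scale, SE 0.05; adjusted p = 7.6e-04). Of the 10 genes with the largest increase, 6 others were crystallins. crygmxl2 rose 2.29-fold, crybb1l3 2.25-fold, cryba2b 2.04-fold, crybb1l1 1.98-fold, cryaa 1.90-fold and cryba1b 1.80-fold. The lens channel mipb rose 2.05-fold from 11.7 ± 1.92 to 24.0 ± 0.648 FPKM and the fatty acid carrier fabp11a 1.85-fold. The largest difference on the log2(FPKM + 1) scale was that of si:ch211-57n23.4, from 11.6 ± 4.17 to 43.9 ± 0.440 FPKM (3.79-fold), but its adjusted p rose to 0.080, 0.077 and 0.12 without chimera replicates 1, 2 and 3.

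Among the largest decreases were chemokines, signals that draw in white blood cells. CXCL8 fell 7.00-fold from 22.3 ± 5.68 to 3.18 ± 0.282 FPKM (-2.46 on the log2 scale, SE 0.15; adjusted p = 0.0019). ccl19a.1 went from 11.9 ± 5.80 to 0.161 ± 0.140 FPKM on 3.99 fragments, a call lost without chimera replicate 1 (adjusted p = 0.062) or replicate 3 (0.091). Of metabolic genes, pck1, an enzyme of glucose synthesis, fell 2.37-fold from 73.6 ± 3.06 to 31.1 ± 0.713 FPKM and the glycogen phosphorylase pygmb 2.4-fold. PNchrM fell 2.53-fold and si:ch211-153b23.5 3.01-fold. A gene record of lye, a skin gene with 5 records of that symbol, fell 2.29-fold, with adjusted p = 0.091 and 0.065 without medaka replicates 1 and 2. The other 3 were 2 records of 5S_rRNA and the microRNA gene ola-mir-10d, each listed at 0 in all chimeras, where poly(A) selection and near-identical copies make the values uncertain. For 1 of the 5S_rRNA records the call was lost without chimera replicate 1, 2 or 3 (adjusted p = 0.18, 0.11 and 0.22), without zebrafish replicate 2 (0.051), and with a pseudocount of 5 (0.12) or deposited FPKM (0.062). That of ola-mir-10d was lost with voom weights (0.088).

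Over 13721 tested medaka genes, 370 rose and 436 fell by limma's moderated test with Benjamini-Hochberg adjustment, 19 and 47 of them by at least 2-fold on the log2 scale. The groups did not overlap for 44.6% of genes, against 20% by chance, and the median over all genes was 0.00 to 2 decimals. These counts depend on single libraries. They were 43 higher and 78 lower without medaka replicate 1, 72 and 91 without medaka replicate 2, 203 and 401 without chimera replicate 1, and 67 and 90 without chimera replicate 3. With all 3 groups in the fit they were 975 and 995, and with voom weights on the implied fragments, added after the data were seen, 842 and 1102. On the deposited FPKM, 337 were higher and 247 lower, so 57.7% of called genes were higher in place of 45.9%.

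In the host lens list 6 of 8 members rose, none fell and the median was 0.86. mipa rose 2.42-fold from 3.63 ± 0.877 to 8.80 ± 0.334 FPKM, beside crygn2, cryba1b and mipb. As many rose when adjusted over the list alone. camera gave adjusted p = 6.1e-06, and adjusted p = 0.31 with an estimated correlation. Neural progenitor and neuron genes also rose, 8 of 16 with none fallen and a median of 0.20. ascl1b, a proneural gene, rose 1.70-fold from 7.92 ± 0.454 to 13.4 ± 0.589 FPKM, and the Notch ligand dlb, its target her4.2 and nkx6.1 rose 1.44-fold, 1.39-fold and 1.73-fold. The calls of these last 3 genes were lost without medaka replicate 1 (adjusted p = 0.092, 0.10 and 0.12) or replicate 2 (0.088, 0.054 and 0.070), and those of her4.2 and nkx6.1 also without chimera replicate 3 (0.060 and 0.057). her4.2 stood at -0.01 on the log2 scale with voom weights. There were 10 risen and 2 fallen when adjusted over the list alone. camera gave adjusted p = 8.6e-05, and adjusted p = 0.26 with an estimated correlation.

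The other 3 lists called higher moved little. In the pigment list 4 of 10 members rose, all of them melanin genes, with a median of 0.19 (adjusted p = 2.6e-04; 0.31 with an estimated correlation). The record TYR rose 1.39-fold, tyrp1a 1.34-fold, tyr 1.25-fold and oca2 1.24-fold, and all 4 calls were lost without medaka replicate 1 (adjusted p = 0.088, 0.15, 0.11 and 0.15), medaka replicate 2 (0.078, 0.15, 0.16 and 0.14) or chimera replicate 3 (0.052, 0.067, 0.14 and 0.14), those of tyr and oca2 also without chimera replicate 1 (0.092 and 0.095). Of 29 cell cycle genes 3 rose, with a median of 0.09 (adjusted p = 2.0e-05; 0.26 with an estimated correlation). These were 2 records of rrm1, at 1.39-fold and 1.19-fold, and fen1 at 1.19-fold, each lost without medaka replicate 1 (adjusted p = 0.062, 0.19 and 0.16) or replicate 2 (0.062, 0.19 and 0.20). The last 2 were also lost without chimera replicate 1 (0.089 and 0.12) or replicate 3 (0.15 and 0.17), and fen1 with voom weights (0.68). In the forebrain list 3 of 17 rose and 2 fell, with a median of 0.15 (adjusted p = 0.035; 0.40 with an estimated correlation). eomesa rose 2.22-fold from 1.04 ± 0.0479 to 2.31 ± 0.0191 FPKM, otx2 rose by 0.36 on the log2 scale, and dlx2 and otx1a fell by 0.31 and 0.27. The calls of otx2, dlx2 and otx1a were lost without medaka replicate 1 (0.10, 0.13 and 0.15), medaka replicate 2 (0.069, 0.10 and 0.14) or chimera replicate 3 (0.071, 0.097 and 0.13), and that of otx1a without chimera replicate 1 (0.080). The forebrain list's call was lost on the deposited FPKM (adjusted p = 0.064), under quantile normalization (0.065), at matched depth (0.061), at a minimum mean FPKM of 5 (0.50), without the cross-mapping filter (0.053), without medaka replicate 1 (0.11), without zebrafish replicate 2 (0.056) and without chimera replicate 2 (0.22). By counts adjusted over the list alone, 4 pigment genes rose, 7 cell cycle genes rose, and 3 forebrain genes rose and 2 fell.

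Innate immune genes were the host list with the lowest median, -0.66, with 6 of 10 fallen and none risen. mmp9, a matrix protease of activated leukocytes and wounds, fell 25.7-fold from 5.82 ± 1.04 to 0.226 ± 0.0393 FPKM, and nfkbiaa, a feedback inhibitor of NF-κB, fell 1.84-fold from 14.1 ± 0.857 to 7.71 ± 0.449 FPKM. irg1, an enzyme of activated macrophages, went from 1.38 ± 0.0843 to 0.0167 ± 0.00771 FPKM on 3.99 fragments. tnfb fell 3.56-fold, a call lost without medaka replicate 1 (adjusted p = 0.10), medaka replicate 2 (0.089) or chimera replicate 3 (0.060), and under quantile normalization (0.090). There were 7 fallen when adjusted over the list alone. camera gave adjusted p = 5.3e-06, and adjusted p = 0.26 with an estimated correlation. The host myeloid list had a median of 0.01 over 11 members, with 1 risen and 1 fallen, a mean of -0.16 and camera pointing downward (adjusted p = 0.77).

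**Figure D3:**
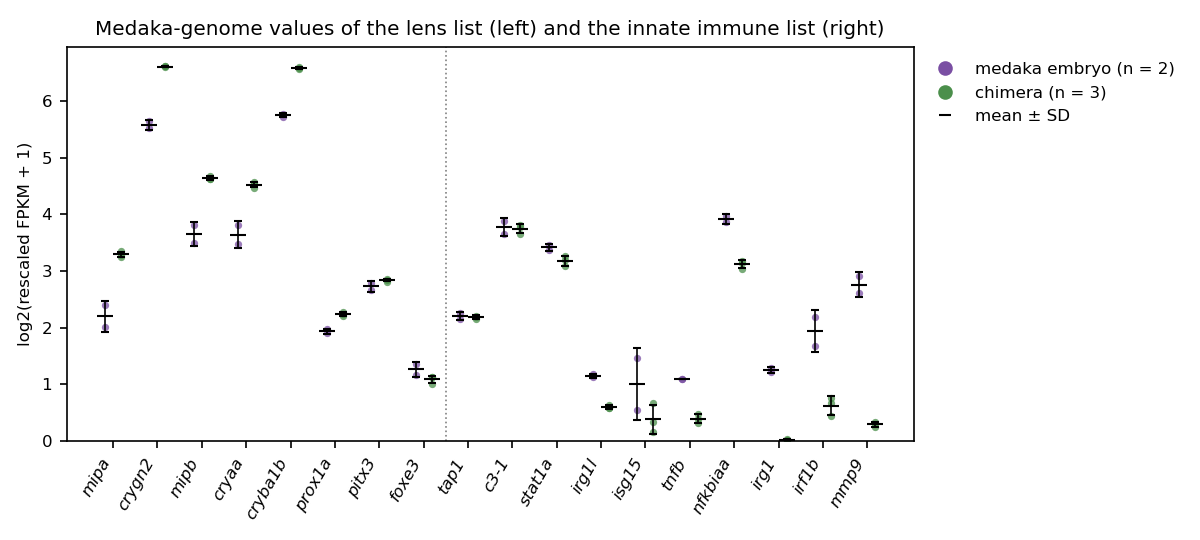
Each point is 1 library's medaka-genome value, as log2(rescaled FPKM + 1), for every tested member of the lens list (left of the dotted line) and the innate immune list (right), in medaka embryos (n = 2) and chimeras (n = 3), with means ± SD as bars. The widest gaps are those of mipa, which rose 2.42-fold, and mmp9, which fell 25.7-fold.

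Further host lists were called lower on small medians. Of 7 pluripotency and maternal genes 5 fell (median -0.44; adjusted p = 2.4e-04; 0.26 with an estimated correlation), including pou5f3 at 1.49-fold, zar1 at 1.80-fold, vox at 1.38-fold and chd at 1.53-fold. The calls of these 4 were lost without medaka replicate 1 (adjusted p = 0.099, 0.063, 0.052 and 0.13), medaka replicate 2 (0.080, 0.098, 0.093 and 0.092) or chimera replicate 3 (0.067, 0.058, 0.059 and 0.093). In the muscle list 6 of 13 fell and 2 rose (median -0.16; adjusted p = 0.0058; 0.26 with an estimated correlation). The members that fell included the myogenic regulators myod1, from 8.18 ± 0.884 to 4.17 ± 0.233 FPKM (1.96-fold), myog (1.60-fold) and myf5 (1.37-fold), whereas cav3, a gene of formed muscle, rose 1.81-fold. Without medaka replicate 1 the calls of myog, myf5 and cav3 were lost (adjusted p = 0.070, 0.063 and 0.051), as was that of myf5 without medaka replicate 2 (0.051) and that of myog without chimera replicate 3 (0.055). At a minimum mean FPKM of 5 the muscle list had adjusted p = 0.059. Of 20 glycolysis and hypoxia genes 7 fell, or 3 on the deposited FPKM and 5 under quantile normalization (median -0.16; adjusted p = 0.0037; 0.31 with an estimated correlation), with eno1a falling 1.65-fold from 298 ± 14.6 to 181 ± 4.40 FPKM. aldocb fell 1.40-fold, epoa 1.52-fold and aldoa 1.26-fold, calls lost without medaka replicate 1 (adjusted p = 0.11, 0.10 and 0.12) or chimera replicate 3 (0.060, 0.058 and 0.097), and for aldocb and aldoa also without medaka replicate 2 (0.086 and 0.12).

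Of 16 posterior hox genes 2 fell, hoxb9a by 0.58 and hoxc8 by 0.37 on the log2 scale (list median -0.17; adjusted p = 2.4e-04; 0.31 with an estimated correlation), and both calls were lost without medaka replicate 1 (adjusted p = 0.20 each), medaka replicate 2 (0.12 and 0.18) or chimera replicate 3 (0.090 and 0.13), and that of hoxb9a without chimera replicate 2 (0.082). Of 11 epidermis genes only 2 records of lye fell (list median -0.17; adjusted p = 0.0020; 0.31 with an estimated correlation), and without medaka replicate 1 the list's adjusted p was 0.075. The records' own calls were lost without medaka replicate 1 (0.091 and 0.15) or replicate 2 (0.065 and 0.14), and the second record's without chimera replicate 3 (0.072). Of the 5 lists, with p adjusted over the list alone, 5 pluripotency, 7 muscle, 9 glycolysis, 5 hox and 3 epidermis genes fell, and 3 glycolysis and 2 muscle genes rose. In the eye field list, 4 of 19 host genes rose, 1 fell and the median was 0.12 (adjusted p = 0.22, or 0.047 without medaka replicate 2; 0.62 with an estimated correlation). The risers were atoh7 (0.92 on the log2 scale), fabp7a (0.59), mab21l1 (0.56) and ccnd1 (0.24), and six3 fell by 0.58. The calls of fabp7a and mab21l1 were lost without medaka replicate 1 (adjusted p = 0.083 and 0.059), and those of atoh7 and ccnd1 without medaka replicate 1 (0.054 and 0.21) or replicate 2 (0.061 and 0.13), and ccnd1 without chimera replicate 1 (0.081) or replicate 3 (0.16). Several small host changes also lost their call with another scaling, filter or depth. On the deposited FPKM these were tyrp1a (adjusted p = 0.051), dlx2 (0.075), otx1a (0.12), the rrm1 record with the smaller change (0.091), aldoa (0.063) and ccnd1 (0.074). Without an expression filter they were tyr (0.052), hoxb9a (0.054), hoxc8 (0.057), the same rrm1 record (0.067), fen1 (0.061) and ccnd1 (0.060), and at matched depth oca2 (0.068), that rrm1 record (0.053) and fen1 (0.069).

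No call was made for 15 further host lists. Adjusted p was 0.072 for notochord (4 of 13 rose), 0.066 for endoderm (2 of 11 rose), 0.27 for heart (1 of 11 rose), 0.28 for ionocytes (1 of 7 rose), 0.15 for heat shock (2 of 16 fell), and 0.67 for p53 (0 of 9 moved). The adjusted p was 0.16 for midbrain and hindbrain, 0.31 for neural crest, 0.35 for erythroid genes, 0.26 for endothelium, 0.58 for hatching gland, 0.72 for yolk genes, 0.61 for presomitic genes and 0.41 for retinoic acid genes. Some passed in single settings: notochord without chimera replicate 1 (0.039), endoderm without chimera replicate 2 (0.048) and at matched depth (0.022), and heat shock without chimera replicate 2 (0.044) and without the cross-mapping filter (0.029). Of 27 host lists, 5 were called higher and 6 lower. None was called with an estimated correlation (lowest adjusted p = 0.26, with 5 under 0.05 before adjustment), and fry called 7 higher and 7 lower. At a minimum mean FPKM of 5 camera called 3 lower, partly because some lists had too few tested members left.

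The third comparison asks whether the change in the chimeras differed between donor and host, gene by gene, over 7789 genes with the same symbol in both genomes. With an estimated correlation, the change of the eye field list was higher in the donor than in the host and that of the epidermis list was lower. The fit assumes the same spread in both genomes, although the median SE was 0.19 in the donor and 0.068 in the host comparison. Each chimera library also enters under both genomes as if independent. In the donor comparison alone neither list passed camera with an estimated correlation (adjusted p = 0.083 and 0.055). Their calls here may therefore rest on the smaller spread of the host values. The lens and muscle lists were lower only with the preset correlation. six7 differed by 3.88 on the log2 scale (SE 0.14; adjusted p = 3.9e-08), at 3.68 in the donor and -0.20 in the host. rorb differed by 3.8, si:dkey-21o19.2 by 4.76, sept4a by 4.52 and zgc:110045 by 3.42. The 5 named genes with the largest lower change in the donor were icn, tnnt3a, ak1, an adenylate kinase, and the crystallins cryba2b and cryba1b. In the chimeras' donor values tnnt3a held under 1 fragment and the other 4 were listed at 0, so no size is given for these differences. In the host cryba2b and cryba1b rose by 1.01 and 0.83, whereas icn was low there, at 0.97 FPKM in medaka embryos and 1.24 in chimeras.

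By limma's test of the interaction 1004 genes had a higher and 2380 a lower change in the donor. Under quantile normalization the counts were 2671 and 1538, and without medaka replicates 1 and 2 the higher genes were 632 and 663. At a minimum mean FPKM of 5 the lower genes were 1295. Across genes, which are not independent replicates, the donor and host changes had a Pearson correlation of 0.09 and a Spearman correlation of 0.17. Of 24 lists 2 were higher and 13 lower in the donor, and 5 held with an estimated correlation. These were the eye field list (13 of 15 higher; median 1.86; adjusted p = 0.044 with an estimated correlation), the cell cycle list (20 of 27 higher; 0.71; 0.031), and the notochord (9 of 9 lower; -3.92; 0.021), heart (8 of 8 lower; -4.06; 0.021) and epidermis (7 of 7 lower; -5.43; 0.021) lists. With donor genes at 0 set to their floor, the medians were -2.76 for notochord (4 genes at 0), -2.50 for heart (7) and again -5.43 for epidermis (2). The lens list had 6 of 7 members lower and 1 higher, with a median of -3.36, or -3.24 with 3 donor genes at their floor (adjusted p = 0.0043; 0.085 with an estimated correlation). Also lower were hox (13 of 13), muscle (9 of 10; 0.085 with an estimated correlation), erythroid (9 of 10), myeloid (5 of 5), pigment (7 of 8), midbrain and hindbrain (10 of 16), endothelium (8 of 11), endoderm (5 of 6) and glycolysis (10 of 16) genes. The median and the test differed in sign for 4 lists without a call, forebrain, heat shock, p53 and innate immune genes.

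The last comparison sets the control embryos of both species side by side, over 10023 genes with 1 record per symbol in each genome. Of the 5 named genes with the largest difference toward zebrafish, 3 were myosin light chain genes. Of these, mylpfa and mylz3 were at 2781 and 1950 FPKM against 0.696 and 0.934 in medaka (means, n = 2 and n = 2; 10.64 and 9.93 on the log2 scale), and myl13 differed by 9.40. The other 2 were fabp1b.1 at 10.20 and icn at 10.19. Higher in medaka were zgc:171226 (1150 against 0.537 FPKM), nme2a (758 against 0.201), the keratin krt15 (4115 against 14), aldh16a1 (885 against 2.96) and eif3bb (174 against 0.0964). By limma's test 4006 genes were higher and 3998 lower in zebrafish, and the levels had a Pearson correlation of 0.72 and a Spearman correlation of 0.68 across genes.

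Of 27 lists compared between the species, 6 were higher in zebrafish. Muscle genes had the largest median, 4.63, with 15 of 19 higher, followed by neural progenitors and neurons (14 of 14; 1.81), lens (10 of 11; 1.72), retinal differentiation (6 of 7; 1.5), forebrain (13 of 16; 1.23) and cell cycle (17 of 28; 0.34). Pluripotency and maternal genes were lower (6 of 7; -1.42). camera's adjusted p ran from 3.0e-04 for neurons to 0.043 for the retinal, cell cycle and pluripotency lists, and none was called with an estimated correlation (lowest adjusted p = 0.87). For pigment and p53 genes, neither called, the median and the test differed in sign. Species, rearing medium and gene annotation differ together in this comparison and cannot be told apart, and the stage is not given.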

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

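All tests of technical explanations here were chosen only after the result was seen, except that of the lift from lost abundant transcripts. The changes in donor and host differed by a test of the interaction for 1004 genes with a higher and 2380 with a lower change in the donor. These counts were 2671 and 1538 under quantile normalization, so the balance of directions rests on the scaling. The interaction test assumes the same spread in both genomes, although the donor values spread more. The lists that differed with an estimated correlation had median differences of 1.86 (eye field), -3.92 (notochord), -4.06 (heart), -5.43 (epidermis) and 0.71 (cell cycle). With donor genes at 0 set to their floor these were -2.76 for notochord, -2.50 for heart and -5.43 for epidermis, so the pseudocount sets part of the size of the first 2. The lens list, with -3.36 (-3.24 at the floor), passed only with the preset correlation. The named genes differed by 4.76 (si:dkey-21o19.2), 4.52 (sept4a), 3.88 (six7), 3.8 (rorb), 3.42 (zgc:110045), -11.11 (icn), -9.48 (tnnt3a), -9.02 (ak1), -8.81 (cryba2b) and -8.58 (cryba1b) on the log2 scale. The last 5 are set by the pseudocount and are not sizes of change, because in the chimeras' donor values tnnt3a held under 1 fragment and the other 4 were listed at 0. On the medaka genome si:dkey-21o19.2, sept4a, six7 and icn were low, so their differences mostly repeat the donor change.

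Signal also appeared where a library has no genome of its own. In units of 1000 fragments, the medaka libraries held 102 and 77.8 on the zebrafish genome, and the zebrafish libraries 63.8 and 81.8 on the medaka genome. In the medaka libraries si:dkey-153m14.1 took 40.3% and 37.2% of this and zgc:158463 23.9% and 28.4%. A cluster of 10 si:dkeyp-3b12 genes on zebrafish chromosome 4 (53793841 to 53897500) held 6815 fragments in medaka replicate 1, against 14.7 in medaka replicate 2 and 21.0, 7.11 and 11.8 in the chimeras. No explanation for this cluster was tested.

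Donor retinal genes were high in the chimeras. Medaka reads at the rate of the medaka libraries would give 0.151% of the chimera fragments of 49 retinal list members, and the eye field median was 1.96 with the zebrafish libraries at the chimera depth. The loss of abundant transcripts, 25.9% of control FPKM over tested genes, would allow a lift of 0.43 for all remaining genes. The eye field median was 1.94 on the deposited FPKM. This lift is rough, because FPKM are scaled to fragments and the lost share of fragments was not worked out. On the deposited FPKM the tested rpl and rps genes had medians of 0.13 and -0.03, whereas a lift of all remaining genes would raise them too. These values argue against cross-mapping and a lift from lost abundant transcripts as the whole cause. Thinning to a common depth keeps the expected FPKM of each gene, so the eye field median could hardly move and depth was not decided by it. A candidate explanation is that the donor cells had mostly become retina, but the cell composition of the donor part was not tested. Its stage against the control embryos, the rearing medium and the transplantation itself were not tested either and stay open. The zebrafish embryos were raised in E3 and the chimeras in ERM, so medium and transplantation cannot be told apart.

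Host lens genes were higher in the chimeras. Zebrafish reads would give 0.105% of the chimera fragments of 12 lens list members. The lens median was 0.88 with all libraries at a common depth, and its lowest value over left-out libraries was 0.76, without medaka replicate 1. These values argue against cross-mapping and a single library as the cause. Depth was not decided, because thinning keeps the expected FPKM of each gene. The host lens may have been larger or further developed in the chimeras, but neither stage nor tissue size is given and this was not tested.

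Host innate immune genes were lower in the chimeras. With fewer myeloid cells the myeloid list should fall alike, but its median was 0.0101 with a median absolute deviation of 0.15 over 11 members, against -0.66 for the innate list. The innate median stayed at or below -0.53 over left-out libraries, the highest being that without chimera replicate 2. The medaka controls may have been in a state of acute inflammation, or the chimeras handled differently, and neither was tested.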

How the results depend on the processing

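Alternatives added after the data were seen are voom weights, thinned libraries, the set over the floor, other cross-mapping rates and the set without small noncoding RNA genes. Of the pairs of a summary value and a setting, 182 stayed within their limits and 33 moved. Of the pairs of gene or list and setting, 4435 kept their side of the threshold, 158 lost a call and 37 gained one. Another 2 changed sign with a call in the main or the other setting. The 4435 include changes of sign between results without a call, such as that of the donor forebrain list under quantile normalization.

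Donor genes higher and lower numbered 5387 and 3307 under quantile normalization. Lower genes numbered 9450 without an expression filter and 3083 at a mean FPKM of at least 5, where the number of genes tested also changes. Over left-out libraries they ran from 628 to 1892 higher and from 3331 to 5514 lower, lowest without a zebrafish library. Host genes lower numbered 247 on the deposited FPKM. Higher and lower numbered 975 and 995 with all 3 groups in the fit, and 842 and 1102 with voom. Over left-out libraries they ran from 43 to 486 and from 78 to 523. For the difference between donor and host they were 2671 and 1538 under quantile normalization, and 1295 were lower at a mean FPKM of at least 5. Over left-out libraries the higher genes ran from 632 to 1159. A lone remaining control is assumed to vary like the other group, and fewer samples explain part of these falls. For the scalings the cause was not tested. No setting moved the species counts by over 1.5 times.

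With an estimated correlation 0 donor and 0 host lists were higher and 0 lower in each, and fry called 23 donor lists lower. At a mean FPKM of at least 5 camera called 3 host lists lower. The muscle list lost its call there (adjusted p = 0.059), and the rest of the fall came from lists with too few tested members left. The donor neuron list had medians of -0.0182 without zebrafish replicate 2 and 0.13 without chimera replicate 1. Host her4.2 was at -0.0136 with voom weights, and the cause was not tested. The zebrafish coefficient of the profile fit was 68.5% of both coefficients with abundant genes weighted down and 73.3% without the 100 most abundant.

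Of host genes named, 32 lost their call without medaka replicate 1, 27 without medaka replicate 2, 27 without chimera replicate 3 and 9 without chimera replicate 1. Donor calls were lost by 6 genes without zebrafish replicate 1 and 7 without replicate 2. No paired analysis was possible because the labels pair no libraries. The accession numbers of chimera replicates 2 and 3 lie apart from those of the other 5 libraries, and whether they were prepared or sequenced separately is not given. For chimera replicates 1, 2 and 3 the summed FPKM of the lens list in the host were 257, 255 and 260 (130 and 143 in medaka), of the innate immune list 33.5, 33.1 and 34.6 (51.2 and 56.2), and of the eye field list in the donor 1637, 1780 and 1659 (420 and 385 in zebrafish). In simulated donor data changes of 2-fold were mostly missed, over the floor as well (1 of 49 raised 2-fold was called). The simulation changed 200 genes, whereas 7122 of 16556 donor genes were called in the data. With so few changed genes the adjusted threshold is stricter, so this recovery does not carry over to the data. Of 1744 donor genes called higher, only 540 rose by at least 2-fold on the log2(FPKM + 1) scale. How far depth limits the donor comparison was therefore not settled by the simulation.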

Other observations

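Gene families were looked at after the data were seen, and the test of a hypothesis at the end was likewise chosen after its result was seen. Among donor genes, collagen genes were low: 41 of 45 tested col genes fell and 1 rose, with a median of -3.26, or -2.90 at the floor (-3.23 on the deposited FPKM and -2.68 under quantile normalization). All 11 keratin (krt) and all 12 annexin (anxa) genes fell, with medians of -3.76 and -4.10, or -2.97 and -3.64 at the floor (-3.13 and -3.58 under quantile normalization). All 20 crygm crystallin genes fell too, with a median of -5.96, or -3.61 at the floor (-5.43 under quantile normalization). Of 19 nucleoporin (nup) genes 11 rose and none fell (median 0.54, or 0.66 under quantile normalization), and of 30 cep genes 14 rose and 1 fell (0.60, or 1.21).

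camera with its preset correlation called 66 of 255 donor families and 1 of 164 host families, the proteasome genes psmd with 2 of 9 risen and a median of 0.13. With an estimated correlation none passed (lowest adjusted p = 0.53 in the donor and 0.99 in the host). Small noncoding RNA genes are recovered poorly by poly(A) selection. In the host 9 of 139 fell and 1 rose. In the donor 57 of 184 were called lower and 1 higher, but no direction is given: 44 of 61 snora, 10 of 15 snord and 21 of 28 dre genes were listed at 0 in all chimeras, and with these at the floor the family medians were 5.02, 5.89 and 7.45.

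The donor cells could have formed the anterior nervous system at large, in which case midbrain and hindbrain genes should be high as eye genes are. The midbrain and hindbrain list had a donor median of -1.46 with a median absolute deviation of 1.78, against 1.89 for the eye field list (-0.79 and 2.32 under quantile normalization). This argues against donor cells that formed the midbrain and hindbrain together as much as the eye. The list pools both regions and its 3 genes at 0 are hindbrain hox genes, so the midbrain by itself was not tested. A contribution to the forebrain alone was not tested apart from the retina.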
